A study of Homo sapiens with 8 samples.

How the data were processed

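Messenger RNA levels were measured by RNA sequencing in 8 libraries of THP-1 cells. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with a NEBNext Ultra RNA kit and sequenced as paired reads on an Illumina instrument, and poly(A) selection is not stated in the sources used here. The submitters' processing notes name Trimmomatic for trimming, STAR, HTSeq 0.6.0 and the build hg38. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The authors deposited 1 table of raw counts per gene symbol for the 8 libraries, not normalised, with 19932 symbols and no row without a gene name. All 19932 symbols occur in GENCODE release 29 (GRCh38), 19907 of them as protein-coding genes and 25 as other types, and coordinates, lengths and GC content were taken from that release. A gene with older symbols in the table, such as the HIST1 histones and WARS, is named as in the table. The list of abundant nuclear noncoding RNAs had 0 members in the table. In 3675 genes all 8 libraries had 0 counts.

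Groups and replicate numbers were taken from the sample titles, 4 control and 4 OE libraries collected at 24 h. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. For every pair of libraries within a group, a chi-square test over genes with at least 10 counts found differences beyond counting noise (chi-square per degree of freedom from 1.93 to 8.17). No library was therefore counted as a repeat sequencing of another. The values were 1.93 to 2.97 between control libraries, 2.38 for OE 1 and OE 2 and 2.01 for OE 3 and OE 4. Across these OE pairs they were 5.85 to 8.17. The test cannot tell repeat preparations of 1 culture from separate cultures, so the OE libraries may be fewer than 4 independent samples.

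Counts were analysed with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 11932 and removed 8000. TMM factors ranged around 0.961 ± 0.00436 (SD, n = 4) in control and 1.04 ± 0.0177 in OE. The comparison used the robust quasi-likelihood fit with group as its term and the Benjamini-Hochberg threshold 0.05, and the common coefficient of biological variation was 5.49%. The SE of a log2 fold change is its size divided by the square root of the F statistic. Shares of counts per library were compared with exact permutation tests of 4 against 4, adjusted over 7 measures. Neither the total counts (exact permutation p = 0.257) nor the number of genes with a count (p = 0.457) passed that test.

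Before the data were examined, 39 gene lists, the tests, the rule for naming genes and most alternatives were fixed. The 36 lists with at least 5 tested members were tested with camera on log2 CPM (prior count 2) at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Members are counted past 0.05 over all genes tested and when adjusted over the list alone. The rule names the 10 largest rises and falls among genes past 0.05 with a mean of at least 1 CPM and groups that do not overlap, the 5 smallest p in each direction, 2 to 4 members per list by smallest p, and IL1B, TNF, CXCL8, CCL2, IFIT1, ISG15, AGO2, GAPDH and ACTB whatever their values. Genes that went against their list, and HLA-DRA and TUBB, were named after their values were seen. Some genes that the rule takes are not reported here.

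On simulated counts with 200 changed genes among 11932, drawn from the means and sizes of these libraries, the OE against control test recovered 46% of genes changed by a factor of 1.2, 84% at 1.5, 94% at 2 and 98% at 4. Of its 173 calls 12 were unchanged genes (6.94%). The libraries held 12209964 to 14819715 counts. In a further draw, added after the data were seen, 6 of the 25 weaker and 20 of the 25 stronger genes changed by 1.2 were recovered, and 6 and 22 at 16 times the depth with the spread between libraries kept. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other low-count filters, a fold threshold, the replicate number as a block and leaving out each library. Added after seeing the data were leaving out OE 1 and OE 2 or OE 3 and OE 4, summing these pairs, leaving out the MHC region, and correcting counts for GC content and transcript length in 20 bins each. The sequence of the fragment was not in the sources used here, so target sites were not searched.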

Results

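RNA was sequenced from THP-1 cells, a human monocytic leukaemia line, 24 h after transfection with mimics of tRF-Gly-GCC-06, a small RNA named as a fragment of the glycine tRNA with the GCC anticodon. The series concerns tRNA-derived small RNAs in acute coronary syndrome, and its design asks how raising this fragment changes the mRNAs of monocytic cells. The 4 libraries with the mimic are called OE here, for overexpression, and were set against 4 control libraries. How the control cells were treated is not given in the sources used here. The control libraries held 12744021 to 14819715 counts and the OE libraries 12209964 to 14084393, over 19932 gene symbols, of which 11932 had enough counts to test. Expression is given as CPM, counts relative to library size after TMM scaling, as mean ± SD with n = 4 per group, and fold changes are OE over control on the log2 scale ± SE.

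Genes of DNA replication and mitosis, ribosomal protein genes and genes of ribosome assembly were higher in OE. Interferon-stimulated genes, MHC class II genes, and genes of the macrophage state, lysosomes and lipid handling were lower. These calls were made with camera at a preset correlation of 0.01 between genes, and with an estimated correlation 0 of the 36 tested lists passed (smallest adjusted p = 0.209). IL1B, which encodes the pyrogenic cytokine interleukin 1 beta, rose from 27.4 ± 1.96 to 92.7 ± 34.5 CPM, while CCL2, a chemokine that attracts monocytes, fell from 60.4 ± 4.46 to 25.6 ± 7.52 CPM. Most changes were small. In edgeR's quasi-likelihood test, 5252 genes passed an adjusted p of 0.05, 2641 higher and 2611 lower, and 3877 of the 5252 had an absolute log2 fold change under 0.5. At an absolute log2 fold change of at least 1, 208 genes were higher and 124 lower. In 4746 tested genes (39.8%) the 4 OE values lay entirely above or below the 4 control values, against 2.86% by chance.

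**Figure D1:**
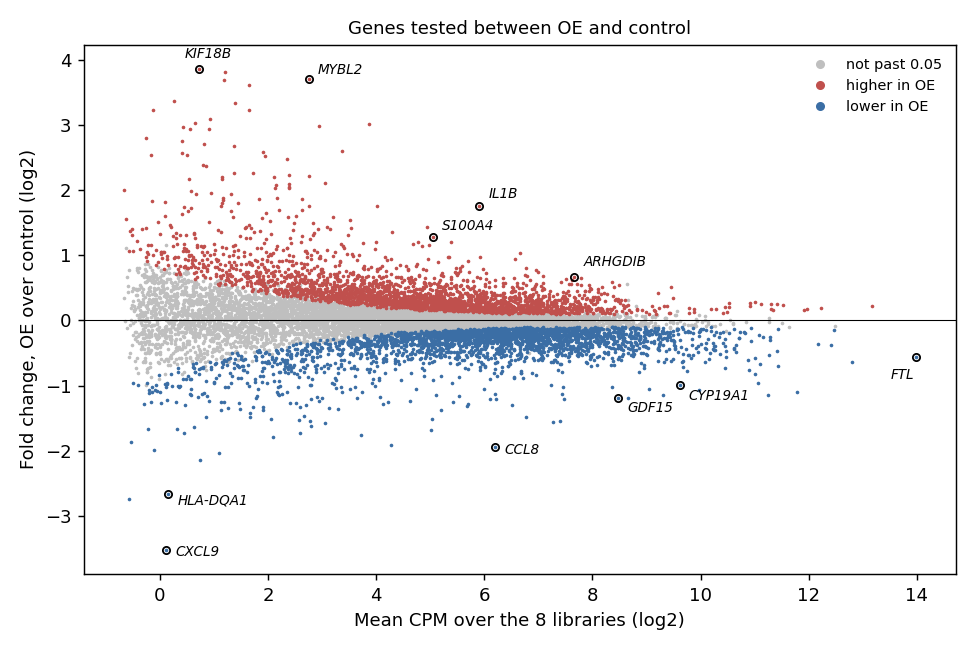
Each point is 1 of the 11932 tested genes, by its mean CPM over the 8 libraries (x axis, log2) and its fold change, OE over control (y axis, log2). Red points (2641) are higher and blue points (2611) lower in OE past an adjusted p of 0.05. KIF18B at 3.87 and CXCL9 at -3.53 mark the extremes of the named genes.

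The cell cycle genes showed the largest rises. Among the 10 genes at the top were KIF18B and ASPM, which act on spindle microtubules, DLGAP5, BIRC5 (survivin) and HJURP, which act in chromosome segregation, and MCM10, PCLAF and DSCC1, which act at the replication fork. MYBL2, a transcription factor of proliferating cells, went from 0.952 ± 0.285 to 12.5 ± 6.07 CPM (log2 fold change 3.70 ± 0.50, edgeR adjusted p = 0.000756). FAM111B, also among the 10, went from 0.471 ± 0.161 to 5.81 ± 2.18 CPM. These genes had fewer than 1 CPM in control, so their fold changes rest on few control counts. KIF18B, on chromosome 17 from 44924709 to 44947711 (GRCh38), had 0.203 ± 0.115 CPM in control and 3.09 ± 2.15 in OE. Its log2 fold change of 3.87 ± 0.74 was 2.51 without OE 1 and OE 2.

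Of 27 tested genes of G1/S and DNA replication, 25 rose and 0 fell, with the same 25 and 0 when adjusted over the list alone (camera adjusted p = 5.60e-10; adjusted p = 0.299 with an estimated correlation). The replicative helicase subunit MCM6 rose by 1.21 ± 0.12 and the replication factor CDC45 by 2.27 ± 0.27. In absolute terms MCM6 went from 16.6 ± 0.48 to 38.3 ± 7.35 CPM. Of 23 tested G2/M genes, 20 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 2.80e-07; adjusted p = 0.299 with an estimated correlation). The mitotic motor KIF11 went from 2.07 ± 0.175 to 8.41 ± 3.22 CPM, the checkpoint kinase TTK from 2.81 ± 0.467 to 6.20 ± 1.37, and the exception was PTTG1 (securin), which fell by 0.35 ± 0.11. The mean of the G2/M members lay 1.71 and 1.80 log2 units above the control mean in OE 1 and OE 2, and 0.94 and 1.02 above it in OE 3 and OE 4. Replication-dependent histone genes did not rise as a list. Of 22 members 11 were tested, of which 7 fell and 1 (HIST1H1C) rose, also when adjusted over the list alone (camera adjusted p = 0.0294; adjusted p = 0.347 with an estimated correlation). Their mRNAs mostly lack a poly(A) tail and poly(A) selection is not stated. Whether these counts reflect the histone mRNAs of dividing cells therefore cannot be told. The histone call was lost without OE 1 and OE 2 (camera adjusted p = 0.0795) and without a low-count filter (0.326). HIST1H2AC fell by 0.38 ± 0.06 and HIST2H2BE by 0.29 ± 0.04.

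Genes of ribosomal proteins and ribosome assembly were higher as well. Of 73 tested cytosolic ribosomal protein genes, 64 rose and 0 fell, or 67 and 0 adjusted over the list alone, with a median log2 fold change of 0.38 (camera adjusted p = 1.77e-18; adjusted p = 0.226 with an estimated correlation). RPS6, a protein of the small subunit, went from 278 ± 8.26 to 397 ± 26.2 CPM, and RPS24, RPS27A and RPL6 rose by 0.46 ± 0.04, 0.53 ± 0.05 and 0.49 ± 0.05. These genes have many processed pseudogenes that can share their reads, so their levels are uncertain, and together they took 0.983% ± 0.034 of the counts in control and 1.35% ± 0.079 in OE (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allows; adjusted p = 0.04 over 7 library measures). All 22 tested genes of ribosome biogenesis rose, also when adjusted over the list alone (camera adjusted p = 2.80e-07; adjusted p = 0.299 with an estimated correlation). Among them NOLC1, a nucleolar phosphoprotein, rose by 0.44 ± 0.06 and POLR1B, a subunit of the polymerase that makes ribosomal RNA, by 0.56 ± 0.09. Of the 13 mitochondrially encoded genes 10 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.000588; adjusted p = 0.299 with an estimated correlation), among them MT-CO3 by 0.25 ± 0.04 and MT-CO2 by 0.24 ± 0.04. Their share of the counts was 3.03% ± 0.045 in control and 3.78% ± 0.099 in OE (exact permutation p = 0.0286, adjusted p = 0.04). Of 31 nuclear genes of oxidative phosphorylation 9 rose, 1 (SDHD) fell and 21 did not pass, with the same 9 and 1 adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.517 with an estimated correlation). ATP5F1A, a subunit of ATP synthase, rose by 0.25 ± 0.05 and CYC1, of complex III, by 0.25 ± 0.06.

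**Figure D2:**
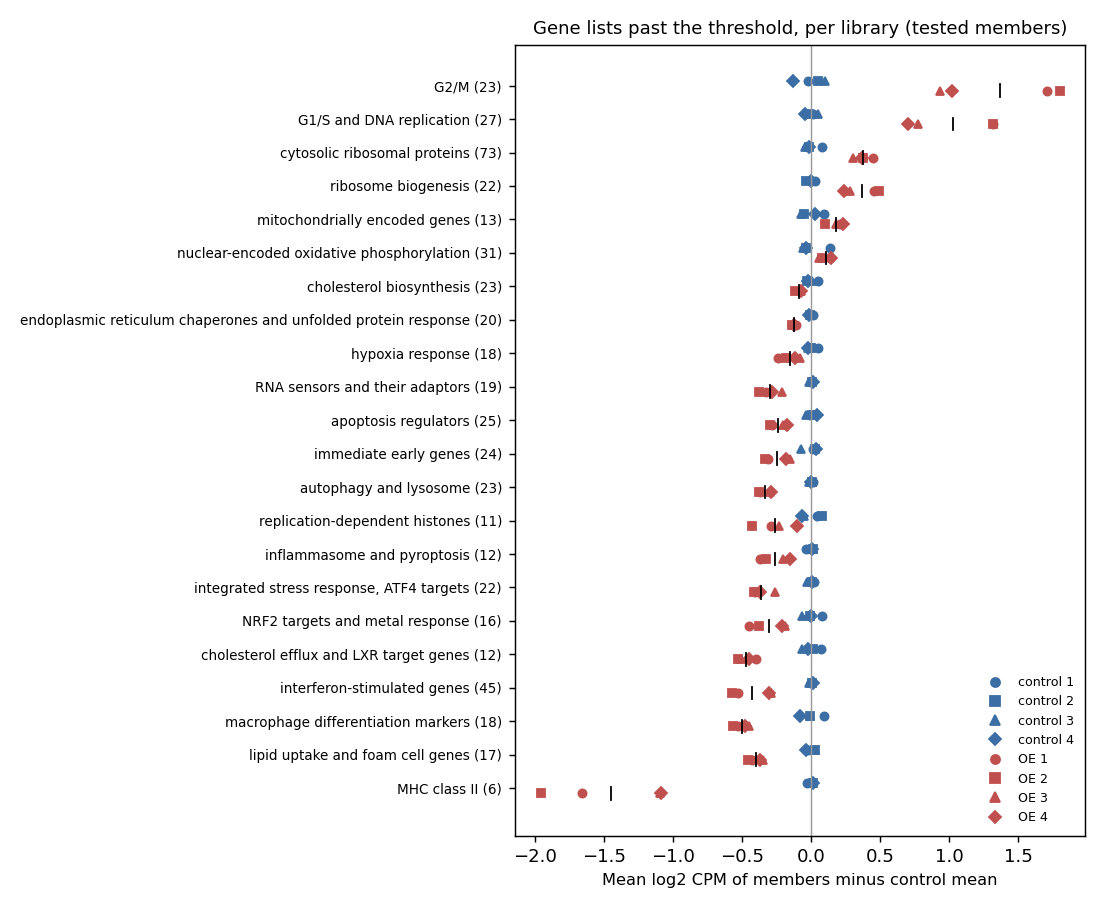
Each row is 1 of the 22 gene lists past the camera threshold, with its number of tested members. Points are libraries (blue control, red OE, shape by replicate), placed on the x axis at the mean log2 CPM of the members minus the control mean, and black ticks mark the OE mean. For G2/M genes OE 1 and OE 2 lie at 1.71 and 1.80 and OE 3 and OE 4 at 0.94 and 1.02.

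Interferon-stimulated genes were lower in OE, from a high level in control. Of 45 tested members 39 fell and 0 rose, or 42 and 0 adjusted over the list alone, with a median log2 fold change of -0.39 (camera adjusted p = 4.99e-14; adjusted p = 0.301 with an estimated correlation). IFIT1, an antiviral protein that binds foreign RNA, went from 3429 ± 94.0 to 2109 ± 338 CPM, and ISG15, a ubiquitin-like modifier, from 1320 ± 76.2 to 853 ± 128. The antiviral GTPase MX1 fell by 0.63 ± 0.05, the mitochondrial kinase CMPK2 by 0.50 ± 0.05 and USP18, which removes ISG15 from proteins, by 0.40 ± 0.04. Per library the members' mean lay 0.53 and 0.58 log2 units lower in OE 1 and OE 2 and 0.29 and 0.31 lower in OE 3 and OE 4. IFNB1, which encodes interferon beta and lies on chromosome 9 from 21077105 to 21077963, went from 2.10 ± 0.193 to 0.631 ± 0.195 CPM. CXCL9, a chemokine induced by interferon gamma on chromosome 4 from 76001275 to 76007488, had the largest fall of the named genes, from 2.00 ± 0.631 to 0.170 ± 0.104 CPM (log2 fold change -3.53 ± 0.43, edgeR adjusted p = 2.71e-06). IDO1, an interferon-induced enzyme of tryptophan breakdown, went from 20.4 ± 3.01 to 6.07 ± 2.43 CPM. Of 19 RNA sensors and their adaptors, 11 fell and 2 (TRAF3 among them) rose, also when adjusted over the list alone (camera adjusted p = 0.00615; adjusted p = 0.299 with an estimated correlation). TLR8, an endosomal receptor of single-stranded RNA, fell by 1.14 ± 0.15, TLR3, which binds double-stranded RNA, by 0.73 ± 0.12 and the DNA sensor CGAS by 0.61 ± 0.07. Inflammasome and pyroptosis genes fell in 7 of 12 cases and rose in 1 (TXNIP), also when adjusted over the list alone (camera adjusted p = 0.00432; adjusted p = 0.319 with an estimated correlation), among them CASP4 by 0.39 ± 0.05 and AIM2 by 0.57 ± 0.07.

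Cytokine and chemokine genes went both ways. Of 18 tested members 7 rose (IL1B, CXCL1, CXCL2, CXCL3, CXCL5, CXCL8 and CCL20) and 8 fell (CSF1, IL1RN, CXCL16, EBI3, IL10, CCL2, CCL7 and CCL8). Adjusted over the list alone the counts were 8 and 8, and the list as a whole did not pass (camera adjusted p = 0.815, in the direction of lower values although its median was 0.07). The genes that rose included neutrophil attractants, CXCL8 from 636 ± 33.8 to 804 ± 39.7 CPM (log2 fold change 0.34 ± 0.05, edgeR adjusted p = 1.01e-05), CXCL1 from 6.55 ± 0.963 to 14.4 ± 1.27 and CXCL3 from 6.35 ± 1.41 to 16.9 ± 2.35. IL1B rose by 1.77 ± 0.30 (edgeR adjusted p = 0.00380), and its 4 OE values all lay above the control values. Its raw counts were 307 to 403 in control, 1653 and 1890 in OE 1 and OE 2, and 858 and 738 in OE 3 and OE 4. IL1RN, which encodes the antagonist of the interleukin 1 receptor, fell from 1378 ± 56.1 to 911 ± 62.3 CPM. The monocyte attractants CCL2 and CCL8 fell by 1.25 ± 0.20 and 1.94 ± 0.32 (edgeR adjusted p = 0.00201 and 0.00305). CSF1, the growth factor of macrophages, fell by 0.66 ± 0.05. TNF had 0 counts in all 8 libraries, but it lies in a chromosome region described below in which nearly all genes lacked counts, so its expression could not be read. NF-kB pathway and feedback genes also split, with 4 higher and 9 lower of 23, the same when adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.153), except, as lower, without OE 3 and OE 4 (0.0298). NFKBIA, the inhibitor of NF-kB, rose by 0.39 ± 0.05, and BCL2A1 and TRAF1 fell by 0.37 ± 0.04 and 0.48 ± 0.07.

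**Figure D3:**
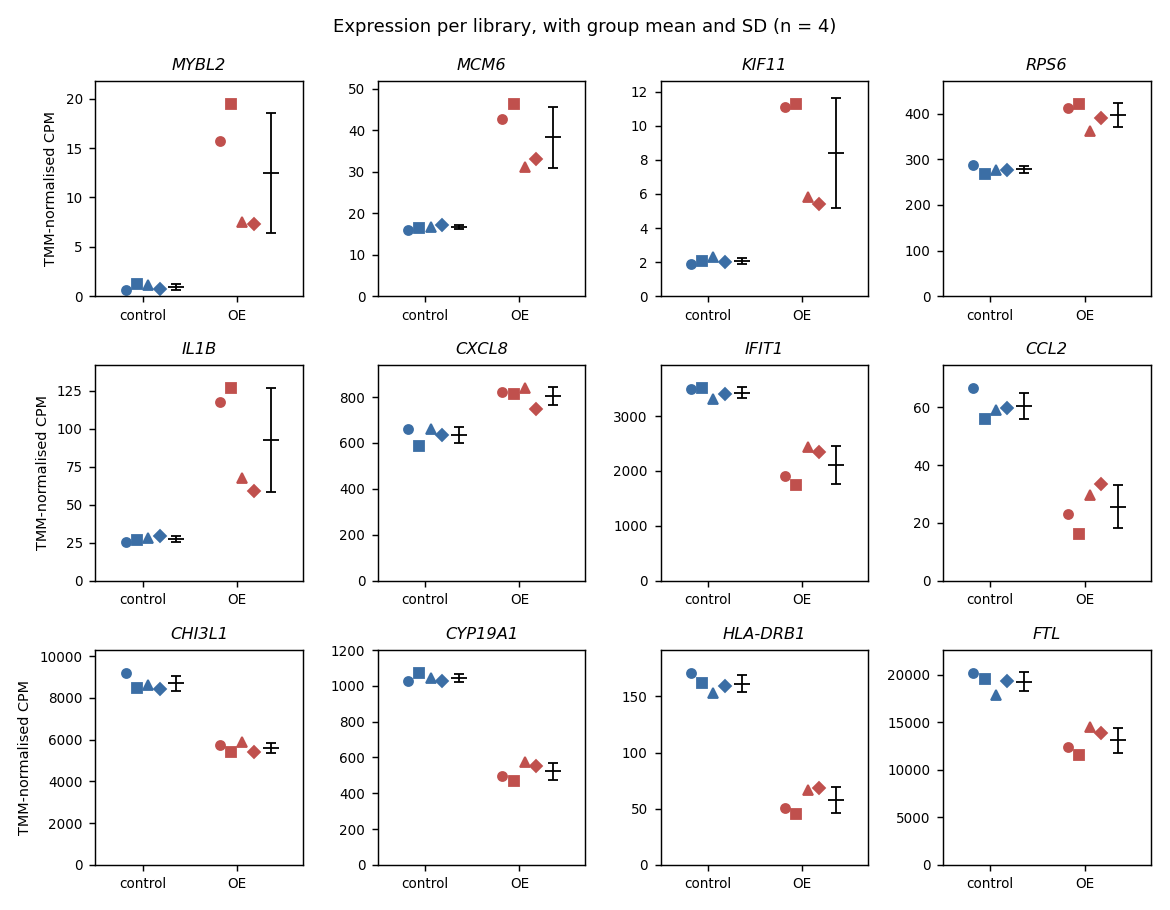
TMM-normalised CPM (y axis, linear, from 0) of 12 genes in the 4 control (blue) and 4 OE (red) libraries, with the group mean and SD in black (n = 4). IL1B has a mean of 27.4 in control and 92.7 in OE, CCL2 of 60.4 and 25.6, and in all 12 panels the OE points lie wholly above or below the control points.

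Genes of the macrophage state were lower. Of 18 tested macrophage differentiation markers 13 fell and 2 (MMP9 and CD163) rose, or 14 and 2 adjusted over the list alone, with a median log2 fold change of -0.46 (camera adjusted p = 3.10e-05; adjusted p = 0.209 with an estimated correlation). The secreted chitinase-like protein CHI3L1 went from 8697 ± 354 to 5610 ± 229 CPM, the chitinase CHIT1 from 23.4 ± 3.40 to 10.3 ± 0.505 and the lipid receptor TREM2 from 685 ± 23.6 to 505 ± 27.5. C1QB, a chain of complement C1q on chromosome 1 from 22652762 to 22661538, went from 6.64 ± 0.878 to 1.90 ± 0.225 CPM. Monocyte markers did not pass as a list (camera adjusted p = 0.327), with 3 of 16 higher and 6 lower, also when adjusted over the list alone. Among them MNDA fell by 0.56 ± 0.07 and CD33 rose by 0.57 ± 0.10.

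Lysosomal and lipid genes fell with them. In the autophagy and lysosome list 16 of 23 fell and 0 rose, or 17 and 0 adjusted over the list alone (camera adjusted p = 2.80e-07; adjusted p = 0.226 with an estimated correlation). The proton pump subunit ATP6V1H fell by 0.51 ± 0.05 and the protease cathepsin D (CTSD) by 0.43 ± 0.05. OSTM1, a lysosomal membrane protein outside the lists, was among the 5 falls with the smallest p, from 310 ± 6.99 to 191 ± 7.79 CPM. Of 17 lipid uptake and foam cell genes 12 fell and 2 (OLR1 and ACAT1) rose, also when adjusted over the list alone (camera adjusted p = 9.11e-05; adjusted p = 0.226 with an estimated correlation). ACAT1 is the gene of that current symbol and not SOAT1, which is a separate member of the list. The lysosomal lipase LIPA went from 2921 ± 70.1 to 2025 ± 105 CPM, and the scavenger receptors MSR1 and CD36 fell by 0.53 ± 0.04 and 0.50 ± 0.05. Cholesterol efflux and LXR target genes fell in 9 of 12 cases and rose in 0, also when adjusted over the list alone (camera adjusted p = 1.02e-05; adjusted p = 0.209 with an estimated correlation). The cholesterol exporter ABCA1 went from 688 ± 19.6 to 534 ± 7.29 CPM, ABCG1 from 9.36 ± 1.43 to 3.36 ± 0.432, and NR1H3, which encodes LXR alpha itself, fell by 0.70 ± 0.06. Cholesterol biosynthesis moved little, with 9 of 23 lower and 0 higher, also when adjusted over the list alone (camera adjusted p = 0.0264; adjusted p = 0.299 with an estimated correlation), and its median of -0.09 became 0.02 when libraries were scaled by their totals. That list did not pass with library totals (camera adjusted p = 0.121) or after correction for GC content and length (0.0796). IDI1 fell by 0.44 ± 0.05 and INSIG1 by 0.27 ± 0.04. The iron storage gene FTL, the most abundant of the named genes, fell by 0.56 ± 0.06 and took 1.85% ± 0.087 of the counts in control and 1.36% ± 0.119 in OE (exact permutation p = 0.0286, adjusted p = 0.04).

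All 6 tested MHC class II genes fell, also when adjusted over the list alone (camera adjusted p = 0.000256; adjusted p = 0.299 with an estimated correlation). HLA-DRB1 went from 161 ± 7.52 to 57.7 ± 11.8 CPM, HLA-DRB5 (chromosome 6, 32517343 to 32530287) from 30.3 ± 2.23 to 8.16 ± 3.13, HLA-DQB1 from 10.4 ± 0.918 to 3.45 ± 1.47 and HLA-DQA1 from 1.92 ± 0.365 to 0.304 ± 0.157. Per library the members' mean lay 1.66 and 1.96 log2 units lower in OE 1 and OE 2 and 1.10 and 1.09 lower in OE 3 and OE 4. Both members outside the MHC region fell too, the invariant chain CD74 by 0.78 ± 0.12 and the class II activator CIITA by 0.59 ± 0.22. Levels of the HLA genes are uncertain, because they resemble each other and because the MHC region on chromosome 6 (29722775 to 33087201) was nearly empty of counts. Among its 137 genes, 6 reached a mean of 1 CPM, against 511 of the other 906 genes of chromosome 6 (Fisher's exact test, two-sided, p = 3.47e-35). The stretch without counts went beyond these limits. From 28431930 to 33457548, between the nearest genes on either side at 1 CPM or more, lay 45 of the other 906 genes, and 39 of these had 0 counts. HLA-DRA had a mean of 0.00981 CPM over the 8 libraries, and the tubulin gene TUBB 0.0101. Of MHC class I and antigen processing genes 6 were testable, of which 2 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.178). As a list they did not pass camera, except, as lower, without OE 3 and OE 4 (adjusted p = 0.0442), but they passed fry, described below (adjusted p = 0.0141). B2M, the light chain of class I molecules, encoded on chromosome 15, fell by 0.47 ± 0.04, ERAP2 fell by 0.47 ± 0.10 and ERAP1, a related peptidase, rose by 0.15 ± 0.04.

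**Figure D4:**
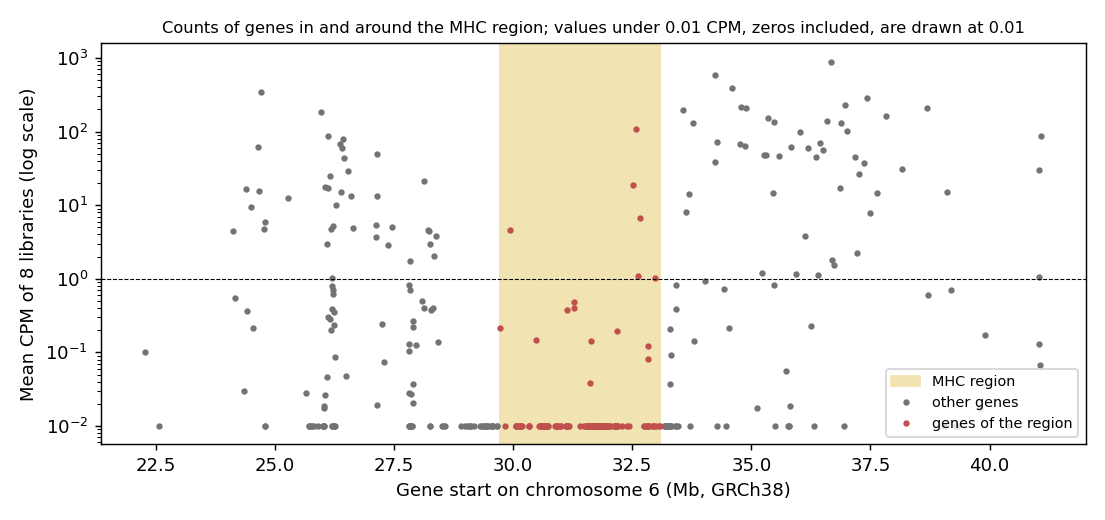
Each point is a gene of chromosome 6 at its start (x axis, Mb, GRCh38) and its mean CPM over the 8 libraries (y axis, log scale, values under 0.01 drawn at 0.01). Red points in the shaded band are the 137 genes of the MHC region, of which 6 reach the dashed line at 1 CPM.

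Among stress and survival genes more fell than rose in every list with TMM scaling, though many did not pass. With library totals the median log2 fold change went from -0.120 to -0.00535 for endoplasmic reticulum genes, from -0.126 to -0.0127 for heat shock proteins and from -0.144 to -0.0308 for hypoxia genes. Of 22 target genes of ATF4 and the integrated stress response, 15 fell and 3 (SLC7A1, SLC7A5 and SHMT2) rose, also when adjusted over the list alone (camera adjusted p = 0.000423; adjusted p = 0.209 with an estimated correlation). ATF4 itself fell by 0.33 ± 0.04, the phosphatase subunit PPP1R15A by 0.48 ± 0.05 and PHGDH, the entry enzyme of serine synthesis, by 0.99 ± 0.13. GDF15, a stress-induced hormone on chromosome 19 from 18374731 to 18389176, went from 493 ± 13.9 to 217 ± 23.2 CPM (log2 fold change -1.19 ± 0.06, edgeR adjusted p = 1.17e-09). Chaperones of the endoplasmic reticulum and the unfolded protein response fell in 10 of 20 cases and rose in 1 (DNAJC3), or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00441; adjusted p = 0.209 with an estimated correlation), with HERPUD1 lower by 0.37 ± 0.05 and CALR by 0.26 ± 0.04. Heat shock proteins did not pass (camera adjusted p = 0.238), with 2 of 12 higher and 5 lower, also when adjusted over the list alone, where HSPD1 rose by 0.32 ± 0.04 and BAG3 fell by 0.35 ± 0.05. NRF2 targets and metal response genes fell in 8 of 16 cases and rose in 1 (NQO1), or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00106; adjusted p = 0.314 with an estimated correlation). TALDO1, an enzyme of the pentose phosphate pathway, fell by 0.39 ± 0.05. Apoptosis regulators fell in 14 of 25 cases and rose in 2 (CYCS and BID), or 15 and 2 adjusted over the list alone (camera adjusted p = 0.000590; adjusted p = 0.226 with an estimated correlation). Those that fell act in both directions, with BAX, which promotes cell death, lower by 0.32 ± 0.06, and BCL2 and BCL2L1, which oppose it, by 0.40 ± 0.06 and 0.29 ± 0.05. Immediate early genes fell in 14 of 24 cases and rose in 3 (EGR1, DUSP2 and BTG2), also when adjusted over the list alone (camera adjusted p = 0.00366; adjusted p = 0.388 with an estimated correlation), with JUN lower by 0.55 ± 0.05, KLF6 lower by 0.79 ± 0.07 and EGR1 higher by 0.55 ± 0.08. Hypoxia response genes fell in 7 of 18 cases and rose in 1 (VEGFA), also when adjusted over the list alone (camera adjusted p = 0.0294, 0.0571 without control 1 and 0.0510 without OE 1 and OE 2; adjusted p = 0.299 with an estimated correlation), and P4HA1 fell by 0.65 ± 0.05.

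Genes of small RNA function changed in few cases. Of 19 tested members of the small RNA machinery 4 rose and 2 fell, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.804). YBX1, a protein that binds tRNA fragments, rose by 0.22 ± 0.04, the exporter XPO5 by 0.21 ± 0.05 and DGCR8, of the microRNA processor, by 0.31 ± 0.07, while PIWIL4 fell by 0.47 ± 0.06. AGO2, the slicing Argonaute, was at 365 ± 11.2 CPM in control and 351 ± 11.6 in OE and did not pass (log2 fold change -0.06 ± 0.04, edgeR adjusted p = 0.266), and its sign turned to 0.06 when libraries were scaled by their totals. AGO2 did pass, as lower, without OE 3 and OE 4 (-0.10, edgeR adjusted p = 0.0217) and after correction for GC content and length (-0.13, adjusted p = 0.00839). Cytosolic aminoacyl-tRNA synthetases had 9 higher and 4 lower of 18, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.609), with WARS, the interferon-induced enzyme for tryptophan, lower by 0.73 ± 0.06 and LARS higher by 0.42 ± 0.06. Cajal body and histone mRNA processing genes had 4 higher and 1 lower of 15, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.437), with NOP10 lower by 0.31 ± 0.04 and NHP2 higher by 0.46 ± 0.13, which did not pass without OE 1 and OE 2 (edgeR adjusted p = 0.0795).

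Further lists split between directions. Of 20 glycolysis genes 7 rose and 2 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.507), and HK2, a hexokinase, fell by 0.83 ± 0.05 while the glucose transporter SLC2A1 rose by 0.43 ± 0.07. Matrix proteases and their inhibitors had 2 higher and 8 lower of 16, also when adjusted over the list alone (camera adjusted p = 0.114, 0.0432 without OE 2 and 0.0376 without OE 1 and OE 2), with TIMP3 lower by 0.69 ± 0.04 and PLAU by 0.76 ± 0.13. MMP13, a collagenase outside that list, was among the 10 largest falls at 9.21 ± 0.584 and 2.85 ± 1.60 CPM. Coagulation and fibrinolysis genes had 5 higher and 3 lower of 12, also when adjusted over the list alone (camera adjusted p = 0.794), with THBS1 higher by 0.66 ± 0.07 and the protein C receptor PROCR lower by 0.91 ± 0.11. Adhesion and migration receptors of monocytes had 6 higher and 5 lower of 16, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.940, in the direction of lower values although the median was 0.005), with CXCR4 lower by 0.88 ± 0.10 and ITGB2 higher by 0.26 ± 0.05. Markers of lymphocytes had 1 higher and 2 lower of 5 (camera adjusted p = 0.701) and those of fibroblasts and endothelium 1 higher and 1 lower of 6 (camera adjusted p = 0.999, in the direction of higher values although the median was -0.03), both with the same counts when adjusted over the list alone. IL7R rose by 0.51 ± 0.11, CD79A fell by 0.60 ± 0.20 and ENG, which monocytes also express, fell by 0.38 ± 0.04. The call of CD79A was lost without control 3, without control 4, without OE 2, without OE 1 and OE 2 or with library totals (edgeR adjusted p = 0.0612, 0.0587, 0.0678, 0.107 and 0.0549). Epithelial markers and erythroid or platelet markers had too few tested members for a list test (2 and 1).

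Outside the lists, the gene with the smallest p was CYP19A1, the aromatase that makes oestrogens, on chromosome 15 from 51208057 to 51338610. It went from 1044 ± 21.8 to 524 ± 47.0 CPM, with a fitted fall of 49.9% (edgeR adjusted p = 4.79e-10). IL18BP, the soluble antagonist of interleukin 18, went from 63.6 ± 3.02 to 28.5 ± 2.51 CPM and the kinase gene PIM1 from 59.6 ± 1.53 to 32.5 ± 0.886. LIFR, a cytokine receptor, and BTNL8, a butyrophilin-like protein, were among the 10 largest falls, at 2.73 ± 0.514 and 0.615 ± 0.129 CPM and at 3.43 ± 0.555 and 0.831 ± 0.0423 CPM. The rises with the smallest p were the potassium channel KCNJ2 (0.69 ± 0.05), the GDP dissociation inhibitor ARHGDIB (0.67 ± 0.05), the RNA editing enzyme ADARB1 (0.65 ± 0.05), the phospholipase PLCB2 (0.58 ± 0.05) and the AMP deaminase AMPD3 (0.50 ± 0.04). KCNJ2 went from 84.9 ± 3.27 to 137 ± 5.05 CPM. Of the reference genes GAPDH rose by 0.13 ± 0.04 (edgeR adjusted p = 0.0118) and ACTB fell by 0.14 ± 0.04 (edgeR adjusted p = 0.0121). ACTB did not pass without control 2 (log2 fold change -0.10, adjusted p = 0.0615) or when libraries were scaled by their totals (-0.03, adjusted p = 0.605) or corrected for GC content and length (-0.08, adjusted p = 0.0801).

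The 4 OE libraries were not alike. On the first principal component, which held 61.1% of the variance, OE 1 and OE 2 lay at 28.6 and 32.0, OE 3 and OE 4 at 10.8 and 11.5 and the control libraries between -22.8 and -18.5, and the labels name no batch. Without OE 1 and OE 2 together 3782 genes passed, and without OE 3 and OE 4 together 6095. The balance of the calls rested on the TMM scaling, since scaling by library totals moved the median of all genes by 0.11 log2 units and gave 4358 genes higher and 1513 lower (74.2% higher, against 50.3%). Of the 36 tested lists 22 passed camera with the preset correlation, 6 higher and 16 lower, and 0 did with an estimated correlation. In fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes, 26 passed, among them heat shock proteins, monocyte markers, matrix proteases and MHC class I genes, which did not pass camera.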

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

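The tests in this part were added after the data were examined, except the splits of the libraries and the scalings, and the dilution test and the form of the test of abundant genes were chosen after the results they measure were seen.

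Genes of the cell cycle rose while macrophage genes fell. Bias by GC content or transcript length did not account for this, since the median log2 fold change of the 50 G1/S and G2/M genes was 1.11 before and 1.14 after correction, and the macrophage median went from -0.46 to -0.42. Nor did the choice among 4 scalings, with a lowest cell cycle median of 1.10 and a macrophage median of -0.35 with library totals. These scalings moved the median of all genes by only -0.00589 to 0.114 log2 units from TMM. They could therefore not have removed changes of this size. Dilution of macrophage-type cells by other cells that lack these transcripts, as the whole cause, would lower all 18 macrophage markers by 1 factor. Their fold changes differed far beyond their errors (heterogeneity Q = 477 with 17 degrees of freedom), and 2 of them, MMP9 and CD163, rose. Calls in both directions were known before this test was written, so it speaks only against such dilution as the whole cause. Dilution beside other changes, or by cells that have some of these transcripts, was not tested. A hypothesis that stays open is that the mimic may shift these cells from a macrophage-like to a more proliferative state. The mimic is the labelled difference between the groups, but how the control cells were treated is not given. An effect of transfection itself therefore cannot be told apart from that of the mimic. A larger share of dividing cells from another source, such as an uneven culture, was not tested.

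Ribosomal protein genes rose by a median of 0.38. After the correction for GC content and length the median kept 106% of its size, so that bias did not account for the rise. With library totals as the scaling the median kept 98.1% when the 20 most abundant genes were left out of the counts (0.485 against 0.495). The 10 most abundant genes took 6.87% of the counts in control and 6.42% in OE, so leaving out such genes could move the median only little. Fewer reads taken by the 20 genes thus did not account for the rise, but a shift over many genes was not examined. An effect of the mimic, or of transfection itself, on ribosomal protein mRNAs may remain as a hypothesis. Reads shared with pseudogenes were not tested for want of the reads.

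The MHC region lacked counts in both groups. Of 31 genes of the region, fixed before their counts were seen and, apart from the class II gene HLA-DRA, in wide use among cells, 0 reached 10 CPM, 29 were under 1 CPM and 20 had 0 counts. Lack of expression in these cells would not empty such a list. Reads lost to alternate haplotype copies of the region in the alignment, where a read with several positions is not counted, are a candidate cause that fits these values, but other ways of losing the region's reads, such as a masked annotation, would give the same. No other biological explanation was tested.

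Other splits of the 8 libraries served as a test of chance. Of the 35 splits into 4 and 4, 1 (the real one) gave as many as 5252 genes, and the highest of the others gave 0. Each other split mixes OE and control libraries, so the difference between them enters the spread within its groups. The 0 is therefore not a measure of how many genes chance would give. Chance can be excluded at 0.05 for the gene count only if the 8 libraries are independent. The labels do not say whether they came from separate cultures, so the splits cannot address chance differences between cultures. For the lists the real split gave 22, reached by 1 of 35 splits, with the same condition. The highest of the others, which exchanged 1 library between the groups, gave 21, so the real split hardly stood out. Splits with 2 control and 2 OE libraries on each side gave 0 to 3 lists, or 5 to 8 where they parted OE 1 and OE 2 from OE 3 and OE 4. The number of lists is therefore weak evidence, and the number of genes stood out by rank alone, as 1 of 35 splits.

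In 10 of 350 combinations of a group with a gene or with 1 of 7 library measures, 1 library lay apart from the other 3 of its group. Chance gives about 1 in 20. All 10 were genes. In control 4 this was BTNL8 at 4.26 CPM (median of the others 3.14), WARS at 640 (609), BCL2L1 at 78.6 (83.3) and FAM111B at 0.232 (0.558). In control 3 it was DSCC1 at 0.628 (0.232), in control 2 ERO1A at 87.3 (88.8) and in control 1 ATP5MC3 at 89.0 (78.0). In OE 2 it was OSTM1 at 180 (195) and TFPI2 at 18.03 (14.4), and in OE 3 CXCL3 at 13.4 (18.2).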

How the results depend on the processing

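The alternatives for pairs of OE libraries, the MHC region, the GC and length correction and the list tests with RLE or upper-quartile factors or without a low-count filter were chosen after seeing the data. The count of 5252 genes stayed within 1.5 times under all tools, scalings, filters and left-out libraries run (3782 to 6095), apart from the fold threshold, where it was 332, with 208 higher and 124 lower, by that setting's construction. Scaling by library totals gave 4358 higher and 1513 lower, as the median of all genes shifts by 0.11. Without each library in turn the count ranged from 4465 to 5401, with 2177 to 2670 higher and 2288 to 2731 lower. DESeq2 gave 4712 genes, of which 4640 were among the 5252 in the same direction, and 3428 of the 5252 (65.3%) passed both without OE 1 and OE 2 and without OE 3 and OE 4. With these pairs summed, 4617 (87.9%) passed. Replicate numbers did not pair the libraries, since same-numbered libraries deviated from their group means with correlations across genes of 0.03, 0.04, -0.04 and 0.07, and the replicate block gave 5247 genes and 22 lists.

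For the lists, 22 calls became 0 with an estimated correlation and 36 with fry's test of change in either direction, which does not compare a list with other genes, and leaving out 1 library gave 21 to 23. Among the named genes, 3612 values under alternatives kept direction and side of the threshold, 14 no longer passed, 2 newly passed and 1 turned its direction, AGO2 at 0.0554 with library totals, where the cause was that scaling's shift. Lists did so in 725, 28, 22 and 16 cases. The 16 turns of direction were in lists that did not pass, and their cause was not tested. They were cytokines and chemokines without a low-count filter and without OE 3 and OE 4 (adjusted p = 0.819 and 0.762), coagulation genes with library totals (0.895), and the small RNA machinery without OE 3 and OE 4 (0.924) and with the GC correction (0.720). Fibroblast and endothelium markers turned with upper-quartile factors (0.950), library totals (0.839), without OE 1 and OE 2 (0.909), without OE 3 and OE 4 (0.940), with the GC correction (0.955) and in fry (0.463). With 1 library left out, adjusted p ranged from 0.872 to 0.951 for adhesion receptors, 0.572 to 0.987 for the small RNA machinery, 0.456 to 0.951 for lymphocyte markers and 0.793 to 0.993 for fibroblast and endothelium markers. A call of cholesterol biosynthesis was lost with library totals (adjusted p = 0.121) and with the GC correction (0.0796), of histones without a low-count filter (0.326) and without OE 1 and OE 2 (0.0795), and of hypoxia genes without control 1 (0.0571) and without OE 1 and OE 2 (0.0510). Calls gained were those of NF-kB genes and MHC class I genes without OE 3 and OE 4 (0.0298 and 0.0442) and of matrix proteases without OE 2 (0.0432) and without OE 1 and OE 2 (0.0376). The low-count filter left 8000 genes untested, 3675 of them with 0 counts in all libraries, and how many of these more depth would bring in was not tested. Changes by a factor of 1.2 were often missed in simulation (46% recovered), but there 16 times the depth raised the recovery only from 52% to 56%. The simulation with 46% gave 173 calls, against 5252 in these libraries, so its Benjamini-Hochberg threshold required a smaller p. It may therefore understate the recovery in these data, and how many such changes were missed here cannot be read from it.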

Other observations

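The gene families below were chosen after the data were seen, by symbol, and tested with camera over 19 families (adjusted p), with the same families' adjusted p with an estimated correlation beside it.

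Families of vesicle and immune effector genes were lower. Several share members with lists of the report, such as CTSB and ATP6V1H with the lysosome list, C1QA and C1QB with the macrophage list and KIF11 with the G2/M list, so these families are not independent of the lists. Of 20 tested subunits of the V-ATPase, the pump that acidifies lysosomes, 14 fell and 0 rose (camera adjusted p = 0.000911; adjusted p = 0.191 with an estimated correlation), and 9 of 13 cathepsins fell and 1 rose (camera adjusted p = 0.000911; adjusted p = 0.191 with an estimated correlation). The cathepsins CTSB and CTSL went from 4829 ± 211 to 2251 ± 351 CPM and from 2806 ± 79.9 to 1449 ± 216 CPM (SD, n = 4). RAB GTPases, which direct vesicle traffic, fell in 24 of 50 cases and rose in 3 (camera adjusted p = 0.000911; adjusted p = 0.191 with an estimated correlation), among them RAB7B and RAB5A. Proteasome subunits fell in 15 of 33 cases and rose in 1 (camera adjusted p = 0.000944; adjusted p = 0.282 with an estimated correlation). Complement components fell in 8 of 11 cases and rose in 1 (camera adjusted p = 0.000944; adjusted p = 0.191 with an estimated correlation), with C1QA going from 17.2 to 7.65 CPM. All 6 tested guanylate-binding proteins fell (camera adjusted p = 0.00208; adjusted p = 0.282 with an estimated correlation), and 4 of 5 Fc gamma receptors fell (camera adjusted p = 0.00208; adjusted p = 0.191 with an estimated correlation). The medians of these families kept their sign with 4 scalings, but with library totals some were near 0, as that of RAB GTPases went from -0.151 to -0.0383, of the V-ATPase from -0.169 to -0.0550 and of the proteasome from -0.137 to -0.0232.

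Among families that rose, 7 of 9 subunits of the CCT chaperonin, which folds actin and tubulin, were higher and 0 lower (camera adjusted p = 0.0257; adjusted p = 0.323 with an estimated correlation). Mitochondrial ribosomal proteins were higher in 27 of 72 cases and lower in 5 (camera adjusted p = 0.00246; adjusted p = 0.282 with an estimated correlation). Nuclear pore proteins rose in 9 of 20 cases and fell in 0 (camera adjusted p = 0.0326; adjusted p = 0.282 with an estimated correlation). Kinesins rose in 14 of 26 cases and fell in 3, and centromere proteins rose in 10 of 19 and fell in 2 (camera adjusted p = 0.00726 and 0.00824; adjusted p = 0.282 for both with an estimated correlation). S100 proteins did not pass as a family (camera adjusted p = 0.161), but S100A4, a calcium-binding protein of motile cells, rose from 19.5 ± 3.13 to 47.1 ± 7.42 CPM (SD, n = 4). APOBEC3 deaminases, with 4 of 6 lower, and zinc finger genes, with 76 of 410 higher and 31 lower, passed camera (adjusted p = 0.0326 and 0.0373; adjusted p = 0.282 and 0.213 with an estimated correlation). Of the zinc finger genes 303 did not pass, and their median log2 fold change was 0.0745, against 0.0184 for all tested genes. Among all 11932 tested genes 2641 were higher and 2611 lower, so zinc finger genes were called higher less often than genes at large. TRIM proteins, translation initiation factors, spliceosome proteins and solute carriers did not (camera adjusted p = 0.161, 0.0650, 0.0653 and 0.883).

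The labels name the cells only as THP-1. Macrophage transcripts were abundant in control, with CHI3L1 at 8697 ± 354 and SPP1 at 5172 ± 90.7 CPM (SD, n = 4). The granule genes MPO, ELANE, AZU1 and PRTN3 together had 2 counts in the 4 control libraries and 0 in the 4 OE libraries. Epithelial markers CLDN7 and MUC1 were at 19.2 and 8.13 CPM in control and the platelet gene PPBP at 1.52.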
